A study of Hordeum vulgare with 18 samples.

How the data were processed

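RNA from whole spikes of barley (Hordeum vulgare, cultivar Golden Promise) was sequenced in 18 libraries, per the labels. The series description speaks of stages of grains, and the tissue given for each sample, whole spike, is used here. They come from 2 transgenic lines in which HvCKX1 was silenced, named KD-CKX1 5.8 and KD-CKX1 17_10 in the labels (line 5.8 and line 17_10 below), and from a control line, each at stages 49 and 59 of the BBCH scale. Each of the 6 combinations of genotype and stage has 3 libraries, which the series description calls biological replicates. Plants grew in field plots at 200 plants per square metre, and 3 µg of total RNA per sample went into a stranded mRNA library kit, per the labels' protocols. Whether one replicate holds spikes of 1 plant or several is not given in the sources used here.

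The deposited signal is a table of gene counts normalized by DESeq size factors by the authors, per the labels, with 1 column per library. The submitters' processing notes list STAR 2.4.2a, Subread 1.5.2 and DESeq2, with no role or order. The genome build, the gene annotation, the strand setting of the counting and the treatment of reads that align to several places are not given in the sources used here. Reads of near-identical gene copies, or of overlapping genes, could therefore be split or lost in ways that these values do not show. Size-factor scaling sets levels relative to the rest of the transcriptome in each library, so a change of total RNA per spike leaves no trace.

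Within each library every value was a whole multiple of the smallest non-zero value, at a tolerance of 0.001 reads for 100% of values, which gave back the whole reads behind the table. The recovered totals ran from 24459652 to 106034579 reads per library. These depths limit the precision for low genes, and a group at 0 was given a floor of 3 reads per library when a fold was stated. Floors and counting intervals cover counting error alone, since PCR copies of a molecule were counted as separate reads.

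The table holds 26066 features, of which 24211 have identifiers beginning with MLOC and 1855 identifiers beginning with EPlHVUG. In 343 of the MLOC identifiers, all of whose numbers begin with 17, a space stands where the others have the sign "_". No identifier matched the reference table of 58438 barley genes (0 of 26066), and the file pairs none with a name. The silenced gene could therefore not be used to check the labels, and the gene lists fixed in advance (pathways and cell type markers) could not be formed. Functions of genes are not described here for the same reason.

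Values were analysed as log2(normalized count + 1), so fold changes understate the change of low genes. Features with a normalized count of at least 10 in at least 3 of the 18 libraries were tested, which left 20874, and 1934 features were 0 in every library. All 18 libraries entered a single limma fit (limma 3.58.1, R 4.3.3) with 6 group means, empirical Bayes moderation with a mean-variance trend, and two-sided tests. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p below 0.05 were counted as changed. Errors printed after ± are SDs over 3 libraries of the normalized counts, and SE is the moderated standard error of a log2 fold change. The comparisons were each line against the control at each stage, stage 59 against 49 in each genotype, 1 line against the other at each stage, and the stage by genotype interaction of each line. The threshold, the fit, the rule for named genes and most alternatives were set before the data were examined.

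Genes are named by identifier. For each comparison of a line with the control, for the stage comparison in the control and for genes changed in both lines, the rule took the 2 largest rises and 2 largest falls. Candidates had an adjusted p below 0.05, a mean of at least 50 normalized counts in the higher group, and no overlap between the replicates of the groups. For genes changed in both lines, the smaller of the 2 changes set the order, and higher genes alone qualified. The rule named 15 identifiers.

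Before use, the fit was tested on simulated data for line 5.8 against control at stage 49, with 50 genes changed at each fold among 20874. It recovered 28% of genes changed 2-fold, 70% of those changed 4-fold, 86% at 8-fold and 88% at 16-fold, with 11 false calls. A simulated comparison with no changed gene gave 0 calls. Each gene was drawn independently, so deviations of a library shared by many genes were left out. False calls that such deviations could cause are therefore not covered by these numbers.

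Replicates were compared before averaging. The chi-square per gene between libraries of one group was at least 37.9, so no library was counted as a copy of another. Replicate numbers paired the libraries in 1 of 15 pairs of groups, control and line 5.8 at stage 49, where the deviations of same-numbered libraries correlated at 0.15, 0.39 and 0.4. With the number as a block, 83 genes changed in that comparison. Comparisons with the same control libraries share their chance values. Overlaps between lines were therefore set beside 100 simulations of unchanged groups against shared controls and beside the overlap of independent lists. A group of 3 control libraries cannot be split into parts of at least 2.

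Alternatives were other pseudocounts (0.5 and 8), no filter and a stricter filter, TMM rescaling, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) on the recovered reads, a fit of the compared groups alone, a minimum fold, the replicate number as a block, and each library left out in turn. Thinning all libraries to the lowest total, the counts of genes changed at both stages of a line or between stages in all 3 genotypes, and the counts of silent genes with their limits were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).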

Results

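Gene expression was measured by mRNA sequencing in whole barley spikes of 2 transgenic lines with a silenced HvCKX1 gene and of a control line. The transgenic lines are KD-CKX1 5.8 and KD-CKX1 17_10, called line 5.8 and line 17_10. HvCKX1 encodes a cytokinin oxidase/dehydrogenase, an enzyme class that degrades cytokinins. Spikes were taken at BBCH stage 49, when the first awns are visible, and at stage 59, the end of heading. Each of the 6 groups had 3 libraries. The recovered depth ran from 24459652 reads (line 17_10, stage 59, replicate 1) to 106034579 reads (control, stage 49, replicate 1). Between 18874 and 19837 features reached 10 normalized counts in a library. The 100 most abundant features took 14.3 to 23.5% of the normalized counts. The features with EPlHVUG identifiers took 7.46% in line 17_10 stage 49 replicate 2 and 0.21 to 2.2% in the 17 other libraries. Of 172 such features tested, 0 passed the threshold in any comparison of a line with the control.

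Stage was the largest source of difference between libraries. The first principal component held 67.2% of the variance of the log2 values. The 9 libraries of stage 49 lay between -158.8 and -86.7 on it, and the 9 of stage 59 between 100.6 and 155.9. The second component held 9.8% and set line 5.8 stage 49 replicate 2 (-154.3) apart from the other 17 libraries. Its mean correlation with the 2 other libraries of its group was 0.926, the lowest of the 18, and it differed from their mean by at least 4-fold in 2183 genes.

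**Figure D1:**
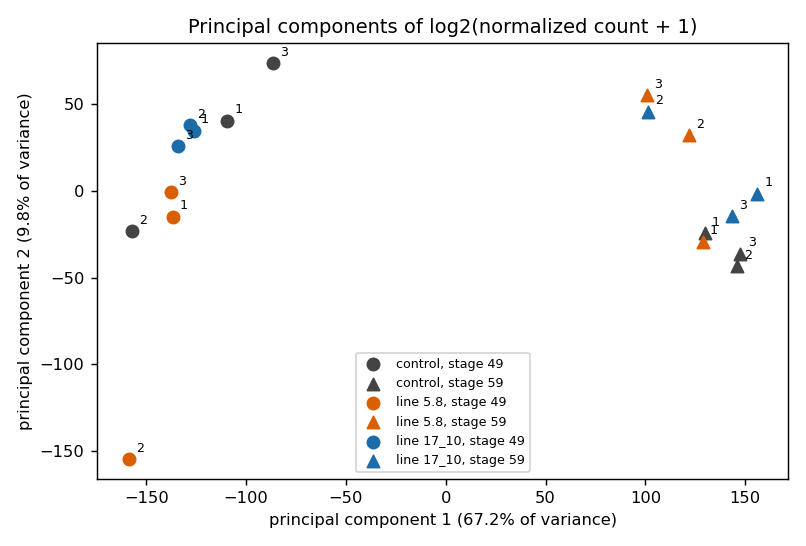
Principal components of log2(normalized count + 1) for the 18 libraries, in arbitrary units with the percent of variance on each axis; colour gives the genotype, shape the stage and the small digit the replicate. Stage 49 lies at -86.7 or below and stage 59 at 100.6 or above on the first component, and line 5.8 stage 49 replicate 2 lies apart at -154.3 on the second.

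The comparison of stage 59 with stage 49 asks how spike transcripts changed over heading. In the control, MLOC_81761 rose from 5.175 ± 7.14 to 10890 ± 3642 normalized counts (SD, n = 3; log2 fold change 11.51, SE 1.18; limma with Benjamini-Hochberg adjustment, adjusted p = 2.9e-06). MLOC_22225 rose from 66.56 ± 75.6 to 118800 ± 62740 (log2 fold change 11.24, SE 1.3, limma adjusted p = 8.2e-06). Among falling genes, MLOC_22196 went from 3676 ± 1579 to 1.418 ± 1.362 (fell by 10.68 on the log2 scale, SE 1.31, limma adjusted p = 1.4e-05). MLOC_74759 went from 2369 ± 1665 to 1.026 ± 1.776 (fell by 10.27 on the log2 scale, SE 1.06, limma adjusted p = 2.9e-06). Both rising genes were also high at stage 59 in the lines, at means of 2310 and 3325 for MLOC_81761 and 19060 and 39070 for MLOC_22225 in lines 5.8 and 17_10. Their spread between replicates was wide, since MLOC_22225 ran from 2060 to 51000 in line 5.8 and from 2300 to 69800 in line 17_10.

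In all, 9392 of 20874 genes changed between the stages in the control (limma, adjusted p below 0.05), 4619 higher and 4773 lower at stage 59. Changes of at least 4-fold were found in 1789 rising and 1692 falling genes. The rising set took 0.8 ± 0.17% of the normalized counts at stage 49 and 8.3 ± 1.2% at stage 59 in the control, whose group means set the fold, and the falling set 12.9 ± 1.34% and 1.9 ± 0.26% (SD, n = 3). In line 5.8, whose libraries entered the choice of the sets through the filter and the shared estimate of spread, the same shares were 0.6 ± 0.14% and 6.5 ± 1.37% for the rising set and 13.1 ± 2.24% and 2.7 ± 0.34% for the falling set. In line 17_10 they were 0.7 ± 0.07% and 6.6 ± 1.36%, and 13.1 ± 0.43% and 2.2 ± 0.8%. Of the genes that rose in the control, 816 had a mean below 10 at stage 49, and of those that fell, 646 had a mean below 10 at stage 59.

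The lines showed stage changes of similar number, with 10532 genes in line 5.8 (5042 higher, 5490 lower) and 9449 in line 17_10 (4485 higher, 4964 lower). A set of 6676 genes changed the same way in all 3 genotypes, 3199 up and 3477 down, where independent lists of these lengths would share 240 and 299. The genotypes share no library in these comparisons. Of the 13255 genes called in at least 1 genotype, 10 were called in opposite directions in any pair. Across genes, which are not independent replicates, the stage fold changes correlated at r = 0.83 between control and line 5.8, 0.93 between control and line 17_10, and 0.89 between the lines. With a minimum log2 fold change of 1, the counts fell to 5838 in the control, 6470 in line 5.8 and 5825 in line 17_10, and the shared set to 4129. A fit of the compared groups alone gave 6743 in line 5.8, 9719 in the control and 10972 in line 17_10.

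Line 5.8 was compared with the control at each stage to find the genes that differ in a line with silenced HvCKX1. At stage 49, MLOC_54756 had 625.5 ± 322.5 normalized counts in line 5.8 and 0 reads in all 3 control libraries (SD, n = 3), at least 246-fold higher against a floor of 3 reads per library (limma adjusted p = 2.8e-09). MLOC_53680 rose from 0.9959 ± 1.117 to 848.1 ± 74.44 (log2 fold change 8.89, SE 0.66, limma adjusted p = 3.9e-06). MLOC_63821 was lower, at 5.587 ± 4.716 against 1935 ± 860.3 (log2 fold change -8.38, SE 0.51, limma adjusted p = 2.9e-07). MLOC_38010 fell from 465.3 ± 60.26 to 23.68 ± 1.064 (log2 fold change -4.23, SE 0.32, limma adjusted p = 4.1e-06). In all, 90 genes changed (64 higher, 26 lower), 68 of them by at least 4-fold. Of the 64 higher genes, 40 had a control mean below 10 normalized counts, and 9 of the 26 lower genes had a mean below 10 in line 5.8. An unadjusted p below 0.05 was reached by 3112 genes, where 1044 are expected by chance if the shared estimate of spread holds for these groups. Without control replicate 2 the count rose to 771, and all 90 genes remained. It was 349 by DESeq2 on recovered reads (213 higher, 136 lower) and 25 in a fit of the compared groups alone (23 higher, 2 lower). Without replicate 3 of line 5.8 the share of higher genes was 53%, against 71.1% with it. On the first component, replicates 1 to 3 of line 5.8 at stage 49 lay at -136.8, -158.8 and -137.4. Those of the control lay at -109.5, -157.1 and -86.7. Whether the 2 groups differed in developmental state within stage 49 was not tested, so the counts cannot be credited to genotype alone.

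At stage 59, MLOC_497 stood at 1575 ± 221.7 normalized counts in line 5.8 and 3.07 ± 3.128 in the control (SD, n = 3; log2 fold change 8.86, SE 0.71, limma adjusted p = 6e-06). MLOC_35134 had 291.1 ± 122.6 in line 5.8 and 0 reads in the control, at least 97-fold higher against the same kind of floor (limma adjusted p = 5.3e-08). MLOC_63821 was again lower, at 34.64 ± 9.99 against 4754 ± 201.4 (log2 fold change -7.1, SE 0.51, limma adjusted p = 2.1e-06). MLOC_60586 was lower at 1.477 ± 1.369 against 125.5 ± 10.81 (log2 fold change -5.87, SE 0.49, limma adjusted p = 8.8e-06). In all, 67 genes changed (48 higher, 19 lower), and 26 of the higher genes had a control mean below 10. The count depended on single libraries. It was 3263 without replicate 1 of line 5.8 (all 67 remained), 184 without control replicate 3 (60 remained) and 43 without replicate 2 of line 5.8 (42 remained). Most calls were then lower without replicate 1 of line 5.8 (1283 higher, 1980 lower) and without control replicate 3 (46 higher, 138 lower), and most were higher without replicate 2 of line 5.8 (37 higher, 6 lower). DESeq2 on recovered reads gave 500 (274 higher, 226 lower).

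Line 17_10 was compared with the control in the same way. At stage 49, MLOC_54756 stood at 440.9 ± 24.12 normalized counts against 0 reads in the control (SD, n = 3), at least 173-fold higher (limma adjusted p = 1.7e-09). MLOC_60700 rose from 0.9541 ± 0.8555 to 517.2 ± 59.86 (log2 fold change 8.16, SE 1.18, limma adjusted p = 0.0042). MLOC_312 was at 1.241 ± 0.5853 against 2311 ± 87.22 in the control (log2 fold change -10.04, SE 0.34, limma adjusted p = 2.7e-10). MLOC_52240 had 0 reads in line 17_10 against 528.4 ± 96.16 in the control, at least 191-fold lower (limma adjusted p = 8.2e-10). In all, 44 genes changed (24 higher, 20 lower), and 17 of the 20 lower genes had a mean below 10 in line 17_10. An unadjusted p below 0.05 was reached by 335 genes, fewer than the 1044 expected by chance. That number assumes that the shared estimate of spread holds for these groups. Spread was uneven: the deviation of a library from the rest of its group had an SD across genes from 0.45 (line 17_10 stage 49 replicate 3) to 1.28 (line 5.8 stage 49 replicate 2). The count was 28 without replicate 1 of line 17_10 (13 higher, 15 lower) and 29 without its replicate 3 (15 higher, 14 lower), and 28 genes remained in each case. It was 28 in a fit of the compared groups alone (10 higher, 18 lower) and 76 by DESeq2.

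At stage 59, MLOC_54756 stood at 157.9 ± 48.43 normalized counts in line 17_10 against 0 reads in the control (SD, n = 3), at least 52.6-fold higher (limma adjusted p = 9.9e-09). MLOC_26429 rose from 6.506 ± 6.341 to 782.5 ± 121.1 (log2 fold change 7.08, SE 0.45, limma adjusted p = 2.4e-07). MLOC_312 was at 0.6849 ± 1.186 against 1532 ± 64.86 and MLOC_52240 at 0.6849 ± 1.186 against 937 ± 47.72 (limma adjusted p = 2.7e-10 and 5.1e-10). Each rested on 3 reads in line 17_10, so the ratio of means was 2240 (95% exact Poisson interval 765 to 10800) for MLOC_312 and 1370 (95% exact Poisson interval 468 to 6630) for MLOC_52240. In line 5.8 these 2 genes stood at 1580 ± 148 and 982.5 ± 51.3. In all, 43 genes changed (22 higher, 21 lower), and 18 of the lower genes had a mean below 10 in line 17_10. The count was 158 without control replicate 3 (39 remained; 22 higher, 136 lower) and 71 without replicate 1 of line 5.8, which enters through the shared estimate of spread (43 remained; 32 higher, 39 lower). It was 26 in a fit of the compared groups alone (9 higher, 17 lower) and 188 by DESeq2 (60 higher, 128 lower), and with no filter on low values the share of higher genes fell from 51.2% to 36.5%.

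**Figure D2:**
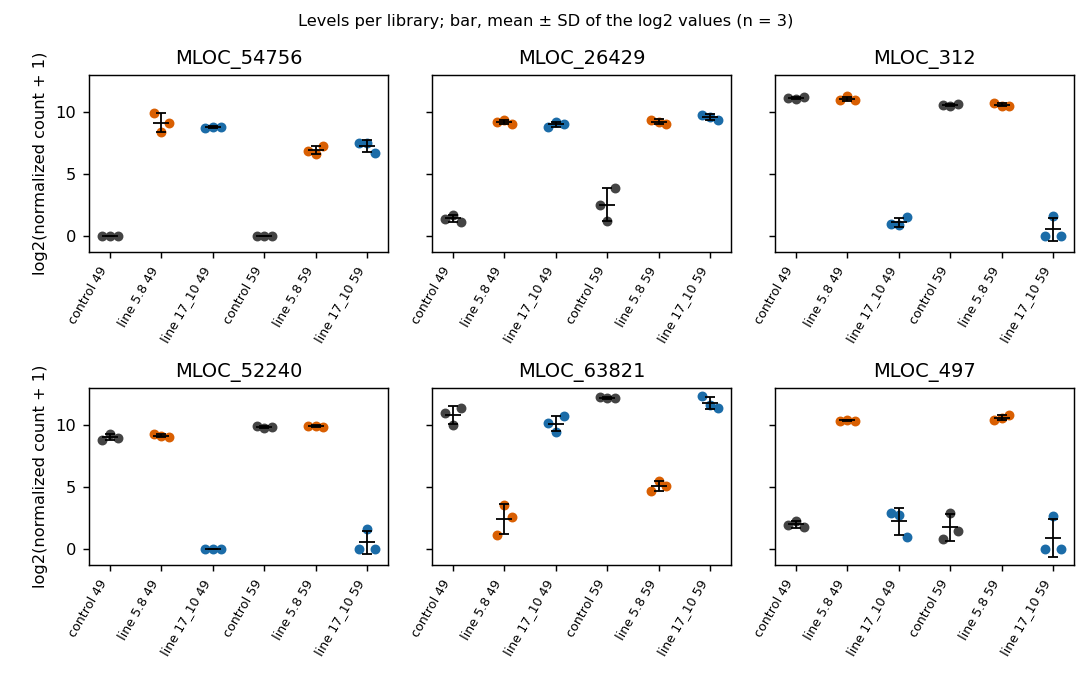
Levels of 6 named genes in the 18 libraries as log2(normalized count + 1), 1 point per library, with bars for the mean ± SD of the log2 values in each group of 3. MLOC_54756 was at 0 in all 6 control libraries, MLOC_312 and MLOC_52240 were near 0 in the 6 libraries of line 17_10, and MLOC_497 was high in the 6 libraries of line 5.8.

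Genes changed in both lines were counted to separate changes common to the 2 silenced lines from those of 1 line. At stage 49, MLOC_54756 and MLOC_53680 were higher in both lines, and MLOC_53680 reached 462.1 ± 24.15 normalized counts in line 17_10 (log2 fold change 8.02, SE 0.66, limma adjusted p = 6.3e-06). At stage 59, MLOC_54756 reached 123.8 ± 27.12 in line 5.8, at least 41.3-fold above the control (limma adjusted p = 7.5e-08). MLOC_26429 reached 606.8 ± 78.5 in line 5.8 (log2 fold change 6.72, SE 0.45, limma adjusted p = 1.2e-06). At stage 49, 16 genes changed the same way in both lines, 15 up and 1 down. At stage 59 there were 17, 15 up and 2 down. No gene was called in opposite directions within a stage. Unchanged groups simulated against shared controls gave a mean of 0.01 genes (highest 1) at stage 49 and 0 at stage 59. With no gene changed in either line and each gene drawn independently, an overlap near 0 was built in. The simulations therefore do not show how much shared controls add to lists that hold real changes. Independent lists would share 0.074 up and 0.025 down at stage 49, and 0.051 and 0.019 at stage 59. Part of the excess may come from the shared controls, which cannot be split here. The overlap at stage 59 was 109 without control replicate 3, 47 without line 5.8 replicate 1, and 11 without control replicate 2 or line 17_10 replicate 2. A fit of the compared groups alone gave 4 and 5, and DESeq2 gave 30 and 107.

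Across all tested genes, the fold changes of the lines against the control correlated at r = 0.31 at stage 49 and 0.67 at stage 59, against 0.501 and 0.499 in the simulations. The covariance was 0.11 at stage 49 against 0.117 in the simulations, and 0.371 at stage 59 against 0.117. The simulated values were built in, since each gene was drawn independently with the same spread in all groups. Deviations of a control library shared by many genes were not simulated. The higher values at stage 59 can therefore not be credited to changes common to both lines. Comparisons that share no library were also set side by side. Line 5.8 at stage 49 and line 17_10 at stage 59 had 15 genes changed the same way, and line 17_10 at stage 49 and line 5.8 at stage 59 had 12. In all, 145 genes were called in at least 1 of the 4 comparisons of a line with the control, and 11 were called in all 4 in one direction, 10 higher and 1 lower. In 7 of these 11 the control mean was below 10.

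The same line was compared between stages to see which differences from the control were present at both. In line 5.8, 45 genes changed the same way at both stages (38 up, 7 down), and in line 17_10 there were 31 (14 up, 17 down). These comparisons share no library. Independent lists would share 0.15 and 0.024 genes in line 5.8, and 0.025 and 0.02 in line 17_10. Of the 90 genes called at stage 49 in line 5.8, 86 had the same sign at stage 59, and of the 44 in line 17_10, 43 did. Over all genes the fold changes at stages 49 and 59 correlated weakly, at r = 0.02 in line 5.8 and 0.29 in line 17_10. In a fit of the compared groups alone the counts were 17 and 16, and DESeq2 gave 87 in line 5.8.

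**Figure D3:**
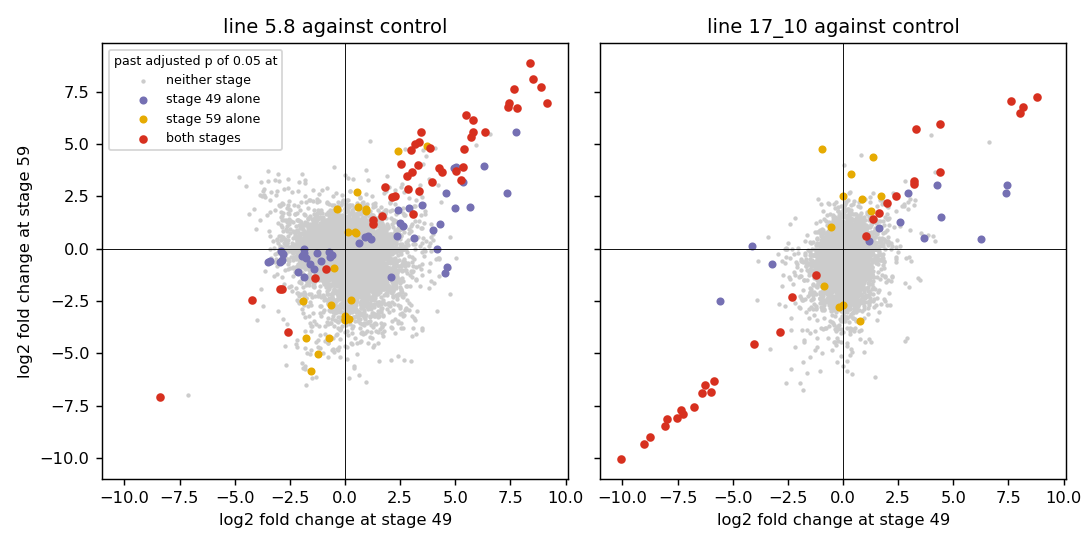
Log2 fold change of each line against the control at stage 49 (horizontal) and at stage 59 (vertical), 1 point per tested gene, coloured by the stages at which the adjusted p was below 0.05. Genes called at both stages, 45 in line 5.8 and 31 in line 17_10, lie in the quadrants where both changes have the same sign.

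The interaction of stage and genotype tests whether the stage change differed between a line and the control. By limma, 0 genes passed for line 5.8 (unadjusted p below 0.05 in 2362 genes) and 0 for line 17_10 (529 genes). By chance 1044 are expected if the shared estimate of spread holds for the groups compared. edgeR gave 0 and 0, and DESeq2 gave 60 and 15. For line 5.8 the limma count was 248 without its stage 59 replicate 1, 44 without control stage 59 replicate 3, and 3 without control stage 49 replicate 2. For line 17_10 it was 25 without control stage 59 replicate 3 and 2 without line 5.8 stage 59 replicate 2.

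The lines were compared with each other because a difference from the control in 1 line alone does not show that the lines differ. MLOC_497 stood at 1350 ± 39.2 normalized counts in line 5.8 and 4.54 ± 3.13 in line 17_10 at stage 49 (SD, n = 3), and MLOC_312 at 2195 ± 267 and 1.241 ± 0.5853. Between line 17_10 and line 5.8, 89 genes differed at stage 49 (27 higher and 62 lower in line 17_10) and 72 at stage 59 (20 higher, 52 lower). Of the 74 genes called against the control in line 5.8 alone at stage 49, 52 also differed between the lines, and of the 28 called in line 17_10 alone, 22 did. At stage 59 the numbers were 34 of 50 and 18 of 26. The same line libraries served to choose these genes and to compare the lines, so the shares are not independent evidence. The count at stage 49 was 135 without replicate 3 of line 5.8 (65 higher, 70 lower), and the count at stage 59 was 1301 without replicate 1 of line 5.8 (all 72 remained; 886 higher, 415 lower). DESeq2 gave 385 and 264, and a fit of the compared groups alone 42 and 41.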

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

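The tests of the shared-control, control-line, sequence-variant and common-response explanations, those of depth and stage for line 5.8 stage 49 replicate 2, all those for the 2 other single libraries, and the look at splits by pairs were chosen after the results had been seen, as was the definition of a silent gene. The tests over splits, of depth for the silent genes, and of genotype and developmental state for line 5.8 stage 49 replicate 2 were written before those tests were run, on patterns already seen.

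The 2 silenced lines differed from each other, by a test of the difference itself, in 89 genes at stage 49 and 72 genes at stage 59 (limma, adjusted p below 0.05). The count at stage 59 was 1301 without replicate 1 of line 5.8, and that at stage 49 was 135 without replicate 3 of line 5.8 (65 higher, 70 lower in line 17_10). One gene, MLOC_60586 (1 of the 145 called), was called in opposite directions in the lines, higher in line 17_10 at stage 49 (log2 fold change 2.6, limma adjusted p = 0.049) and lower in line 5.8 at stage 59 (-5.87). Line 17_10 exceeded line 5.8 for it by 4.13 at stage 49 and by 7.12 at stage 59 on the log2 scale (SE 0.49 each, limma adjusted p = 0.00032 and 6.2e-07).

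A set of 13 genes was nearly silent in line 17_10, below 5 normalized counts in all 6 of its libraries and at least 20 in all 12 others (7 genes with limits of 2 and 50). All 13 were called lower at both stages, with a median of 305.3 normalized counts in the other libraries and 39 reads in total in line 17_10. Lower depth is argued against by the levels, with means of 0 to 1.754 in line 17_10 and 69.74 to 1904 in the others. After thinning, 13 of 13 kept every other library above every line 17_10 library, which the limits used to choose them all but fixed. For chance, 1 of 100 sets of 6 libraries, the real one, gave as many (highest other 0). The draws left out the other sets of 1 genotype (1 silent gene in the control, 0 in line 5.8). The pattern was also picked from these data, so the draws do not exclude chance. A response to silencing common to both lines is argued against too: genes chosen without line 5.8, silent in line 17_10 and at 20 or more in all 6 control libraries, numbered 13, and 0 of them were called lower in line 5.8, where all 13 reached 20 in every library. Reads lost because of sequence variants in the line cannot be told apart from absent transcripts, because at 0.0944% of the other libraries' level both would leave almost nothing, and a loss of the genes in this line is an untested hypothesis.

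Genes changed the same way in both lines could reflect the silencing, chance values of the shared control libraries, or a difference carried by the single control line. Shared chance values are argued against as the whole cause, though not as a part of the overlap within a stage, since line 5.8 at stage 49 and line 17_10 at stage 59, which share no library, had 15 genes in common. Other assignments of the 9 libraries of a stage to 3 groups rarely gave as many genes: 4 of 100, the real one included, reached 16 at stage 49 (highest other 50), and 3 of 100 reached 17 at stage 59 (highest other 36). Both shares lie under 0.05, but the highest others exceed the real counts, which points to a structure of the samples, and the draws ignored the replicate numbers. A difference carried by the control line stays open and cannot be told apart from silencing, because there is 1 control line and 1 of the 11 genes called in all 4 comparisons differed between the lines. The overlap at stage 59 was 109 without control replicate 3, 47 without line 5.8 replicate 1, and 11 without control replicate 2 or line 17_10 replicate 2.

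Single libraries stood apart from their group, and the counts for line 5.8 moved with them (90 to 771 without control stage 49 replicate 2, and 67 to 3263 without line 5.8 stage 59 replicate 1). A wrong label is argued against: control stage 49 replicate 2 had 1 of 17 genes that separated line 5.8 from the control at stage 59 (15 to 16 in line 5.8), line 5.8 stage 59 replicate 1 had 17 of the 21 from stage 49 (0 to 3 in controls), and line 5.8 stage 49 replicate 2 had 5 of 6 genes otherwise found in line 5.8 alone. For line 5.8 stage 49 replicate 2, low depth (rank 11 from the lowest of 18) and the other stage (-158.8 on the first component) are argued against as well. An earlier developmental state stays open for it. Its deviation had an r of -0.02 across genes with the stage change of line 17_10. That measure follows the change from stage 49 to 59, so a state before stage 49 can escape it. The value of -158.8 was also the lowest of the 18 libraries. An earlier developmental state is a candidate explanation for control stage 49 replicate 2 (r = -0.37, negative where genes that rise with stage are low). As limits, line 17_10 stage 59 replicates 2 and 1 reached -0.47 and 0.36, and the 0.36 of control stage 49 replicate 3 is not separate from the -0.37. A later state stays open for line 5.8 stage 59 replicate 1, whose r of 0.11 lies inside that spread. This library was at 128.7 on the first component, against 121.9 and 100.6 in replicates 2 and 3. MLOC_22225, which rose with stage in the control, was at 51050 in it against 2064 and 4054. Field position, harvest time and RNA handling were not tested.

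For comparisons of 3 libraries with 3, only 10 splits exist, too few for a share under 0.05. For line 5.8 at stage 49, 2 of the 10 splits gave at least 90 genes. The other split set control replicates 1 and 3 and line 5.8 replicate 3 against the remaining libraries and gave 1943, which points to a structure of the samples. In this comparison replicates of one number deviated together, and the real split is among 4 that part all 3 such pairs. The 3 others of these gave 0 genes, with and without the number as a block (real 90 and 83), whereas the split with 1943 parts 1 pair. With 4 such splits the smallest possible share is 1 of 4, so they do not exclude chance. The 3 others also place genotype differences inside the groups, which widens the spread and lowers their counts. For line 17_10 against line 5.8 at stage 59, 2 of 10 reached the real 72. The other one, with line 5.8 replicate 1 beside line 17_10 replicates 1 and 3, gave 1164, again a structure of the samples. On the first component, which separated the stages, these 3 libraries lay at 128.7, 155.9 and 143.5. The libraries set against them (line 5.8 replicates 2 and 3, line 17_10 replicate 2) lay at 121.9, 100.6 and 101.2. Whether an uneven developmental state within stage 59 gave the 1164 was not tested. In the remaining comparisons 1 of 10, the real split, gave as many. The real and highest other counts were 44 and 1 for line 17_10 at stage 49, 67 and 6 for line 5.8 at stage 59, and 43 and 13 for line 17_10 at stage 59. They were 89 and 0 between the lines at stage 49. For stage they were 9392 and 1 in the control, 10532 and 170 in line 5.8, and 9449 and 1 in line 17_10.

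Line and control labels were exchanged within each stage. In line 5.8, 1 of 100 splits, the real one, gave the 45 genes changed at both stages (highest other 1). The same held for the 31 genes in line 17_10 (highest other 0). This argues against chance for both without excluding it, since 1 of 100 is the smallest share these splits can give. Exchanged labels also place differences between genotypes inside the groups, which widens their spread and lowers the other counts. For the interactions the real count was 0, which every one of the 100 splits reaches by construction, so the splits say nothing about chance there. The highest other counts were 436 for line 5.8 and 60 for line 17_10, which points to a structure of the samples. By edgeR these interactions gave 0 and by DESeq2 60 and 15, with an unadjusted p below 0.05 in 2362 and 529 genes by limma.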

How the results depend on the processing

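Thinning to the lowest library total, the counts at both stages and in all 3 genotypes, and the counts of silent genes were chosen after seeing the data. All 23 values of named genes kept their direction and their side of the threshold under every alternative run for them (667 of 667 values). The named genes were chosen for large changes without overlap of replicates, so the outcome for their values was nearly fixed. The call of MLOC_60586 in line 17_10 at stage 49 (limma adjusted p = 0.049) was not among the 23 values. Of 470 alternative counts, 54 moved by more than 1.5 times. The cause of a shift was not tested unless named. DESeq2 on recovered reads called more genes, with 349 and 76 for lines 5.8 and 17_10 at stage 49, 500 and 188 at stage 59, 385 and 264 between the lines, 60 and 15 for the interactions, 30 and 107 in both lines at stages 49 and 59, and 87 at both stages in line 5.8. A fit of the compared groups alone gave 25 and 28 for lines 5.8 and 17_10 at stage 49, 26 for line 17_10 at stage 59, 42 and 41 between the lines, 6743 for stage in line 5.8 (but 9719 in the control and 10972 in line 17_10), 4 and 5 in both lines, and 17 and 16 at both stages. A minimum log2 fold change of 1 gave 5838, 6470 and 5825 for stage in control, 5.8 and 17_10, and 4129 shared. With no filter, 28 genes were shared by both lines at stage 59, and each interaction had 1. The interaction of line 17_10 had 2 at a pseudocount of 8. After thinning it had 1, and 11 genes were shared by both lines at stage 59. Limits of 10 and 20 gave 10 genes present in line 5.8 alone (main 5) and 2 silent in control (main 1). Limits of 2 and 50 gave 7 silent in line 17_10 (main 13) and 1 in line 5.8 alone.

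With each of the 18 libraries left out in turn, counts ran from 67 to 771 for line 5.8 and from 28 to 43 for line 17_10 at stage 49. At stage 59 they ran from 43 to 3263 and from 29 to 158. Between the lines they ran from 67 to 135 at stage 49 and from 55 to 1301 at stage 59. The interactions ran from 0 to 248 in line 5.8 and from 0 to 25 in line 17_10, and the overlap of both lines at stage 59 from 11 to 109. Stage counts stayed between 7712 and 10638. With no filter, the share of higher genes moved from 71.6% to 58.1% for line 5.8 and from 51.2% to 36.5% for line 17_10 at stage 59. Without control replicate 3 these shares were 25% and 13.9%, by DESeq2 54.8% and 31.9%, and for line 5.8 without its replicate 1 39.3%. At stage 49, line 17_10 exceeded line 5.8 in 30.3% of the genes that differed, and in 48.1% without replicate 3 of line 5.8. For line 5.8 against the control at stage 49 the share of higher genes was 71.1%, 53% without that replicate and 92% in a fit of the compared groups alone. TMM rescaling, the scaling alternative, moved no such share by over 10 percentage points.

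Across the series the replicate number did not pair the libraries. Of 45 same-numbered pairs, 13 had a correlation of deviations over 0.1 (range -0.28 to 0.4), and 6 of 18 libraries correlated best with their own number. The exception, 1 of 15 pairs of groups, was control and line 5.8 at stage 49 (0.15, 0.39 and 0.4). With the number as a block, the counts were 83, 40, 56 and 39 for the comparisons of lines 5.8 and 17_10 with the control at stages 49 and 59, and no count moved by more than 1.5 times. Gene set tests with a preset or estimated correlation were not run, since no list could be formed. Simulated data at the sequenced depth gave back 28% of 2-fold changes, a limit in which depth and the spread of 3 replicates were not separated. After thinning, the counts of the lines against the control were 78 and 35 at stage 49 and 59 and 32 at stage 59.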

Other observations

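The limits that define silent and present genes, and the look at single features, were chosen after the data had been seen. Some genes were present in 1 genotype alone or absent from it. In line 5.8, 5 genes were at 20 or more normalized counts in all 6 libraries and below 5 in the 12 others, with means of 332.1 for MLOC_35134, 208.8 for MLOC_75680, 194.2 for MLOC_31213, 71.84 for MLOC_80629 and 55.57 for MLOC_35341. Their levels in the 12 other libraries were 0.05707 to 1.432 on average. Limits of 10 and 20 gave 10 such genes, and limits of 2 and 50 gave 1. MLOC_54756 was the 1 gene absent from the control by these limits, with 0 reads in 6 libraries and a mean of 337 in the 12 others (2 genes with limits of 10 and 20). Line 17_10 had no gene of its own (0), and line 5.8 had no gene missing in it alone (0).

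Other genes switched with stage in every genotype. By the same limits, 62 genes were silent in all 9 libraries of stage 49 and present in all 9 of stage 59, and 28 genes did the reverse. With limits of 10 and 20 these counts were 112 and 76, and with limits of 2 and 50 they were 5 and 6.

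The 7.46% of normalized counts taken by EPlHVUG features in line 17_10 stage 49 replicate 2 lay mainly in a pair of features, EPlHVUG00000010090 at 4.98% and EPlHVUG00000010111 at 2.23%. In the other 17 libraries the first took 0.113% to 1.41% and the second 0.0395% to 0.615%. Within line 5.8 at stage 59, replicate 1 was at 0.113% for the first feature and replicates 2 and 3 at 1.01% and 1.03%.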
